A study of Homo sapiens with 4 samples.

How the data were processed

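RNA from 293 T-REx cells was hybridised to 4 dual-colour Agilent whole human genome arrays of 43931 features each, of which 2256 were control features, and the others held 41000 distinct probes of 60 bases. Per the labels, the scrambled control of each hairpin was labelled with Cy5 (red) and the shRNA sample with Cy3 (green) on every array. Total RNA was extracted with a phenol-based reagent and the cells were grown in medium with 10% fetal calf serum, per the labels' protocols. The deposited scanner files hold the spot intensity of each channel, its local background, flags and Feature Extraction's own log10 ratio with a p-value, per the file headers. Feature Extraction 9.5.1.1 made them on a grid built for hg17, per the file headers. The deposited value table holds the log10 ratio of red over green. It was set against the stored log10 ratio of the scanner files and matched it in scale, direction and centring within 1e-06, except for 296 values that had lost their decimal mark and 8 others. Its listed-as-missing values are those with a scanner ratio of exactly 0, and its column medians are 0.0222, 0.014, 0.0157 and 0.01275. Some scanner values use decimal commas and were read as such. For 38 features the gene name had been turned into a date by spreadsheet software, and accessions were used for naming.

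The columns of each row were then compared with each other, by limits chosen after the data had been seen. A stored log10 ratio that was not 0 departed by more than 0.01 from the ratio of the 2 processed signals of its row at 15, 17, 9 and 16 of 41675 probe spots on the MYC and PIM1 arrays in order. Of these 57 ratios, 55 lay lower for the shRNA than the signals gave, each at least 2-fold below the control. A mean signal of more than 100 over background departed from the processed signal by more than 0.5 (log2, from the smooth relation of the array, whose spread was 0.018 to 0.078) or was not called above background at 17 spots. Both mean and both processed signals were identical to those of another spot at 23 spots, in 11 sets, 10 of which span more than 1 array. Together 82 spots met a limit, and they involve the probes used for 37 genes, including MYC, PIM1 and FOSL1, the last on all 4 arrays. The sources used here do not say how these values arose. They were kept in the comparisons, as fixed beforehand, and left out in an added alternative.

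Probes were named through a table of RefSeq genes, 23434 by accession, 2317 by symbol and 1038 by an older symbol. The other 14211 of 41000 probes stayed unnamed. Coordinates are those of the files and no genome of that build was used.

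Mean signals were background corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 under R 4.3.3. Control spots had weight 0, and 66, 47, 44 and 81 spots per array with outlier flags were left out. Spots of a probe were averaged. The log2 ratio was taken as shRNA over scrambled control on every array. A probe was kept if it was well above background in 1 channel on both arrays of a target, which left 28105 probes and 13787 named genes. The brightest kept probe stood for a gene, and 4506 genes had more than 1 kept probe.

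All 4 arrays entered a limma fit with a mean per target, which share an estimate of the spread (2 residual degrees of freedom, 3.05 prior degrees of freedom, prior SD 0.138). Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Because each target has n = 2, the calls rest on the spread pooled over genes and arrays. The 28 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 28 lists. Named genes are MYC, PIM1, FOSL1 and ID2, the 8 highest and 8 lowest changes of each contrast among genes past the threshold that agree in sign on both arrays, filled up by size where fewer passed, and up to 3 members of each list with the smallest p. ALDOA and CEBPA are named by the list part of that rule. EGR2, JUN and HSP90AA1 are named by the first part. Some genes that the rule names are not reported here.

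The fit and the list test were run on simulated log2 ratios of 13763 genes with 200 genes changed. Normalisation was not simulated, and the genes were drawn independently of each other. In the data 1706 genes were called with MYC shRNA, so the adjustment there differs from that of the simulations. At 2-fold the fit recovered 78.4% of the changed genes for MYC, 80.7% for PIM1 and 0% for the difference. At 4-fold it recovered 98.5%, 96.7% and 92.6%. At 1.5-fold it recovered 0% for each. At 2-fold 5.54% and 5.72% of the calls for MYC and PIM1 were false, and 100% of the few for the difference, while at 4-fold the false share was 4.55%, 5.75% and 4.63%. A list of 30 genes shifted by 0.5 was found in 5 of 5 simulations for each comparison, and 0 of 135 unshifted lists were called. The simulated genes were uncorrelated, whereas estimated correlations within the lists of the data reached 0.366. These simulations therefore do not show how often correlated lists are called falsely.

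Alternatives were no background subtraction, Agilent's processed signals, a normexp offset of 16, median centring, scaling between arrays, no filter or a stricter filter on dim probes, outlier spots kept, the mean of all probes of a gene, removal of the GC trend of the probes, the deposited value table, each array left out in turn, an intensity trend with robust fitting, TREAT at 1.2-fold, an adjusted p under 0.1, a fit of the target's arrays alone, a separate-channel fit (intraspot correlation 0.556), Feature Extraction's own p under 0.01, the hairpin number as a replicate block, and 2-fold in place of 1.5-fold. Testing all probes, leaving out probes of at least 40% cytosine and leaving out spots whose columns disagree were added after the data had been seen. Intervals of ratios in the closing tests come from 2000 bootstrap draws over genes, or over the unnamed probes in the test of cytosine. Each array lies on its own slide, so no slide or scan batch could be told apart from an array. Numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15 read the files and drew the figures.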

Results

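Gene expression was measured in human 293 T-REx cells, an embryonic kidney line that carries the tetracycline repressor, after RNA interference against MYC or PIM1. MYC is a transcription factor that drives growth genes, and PIM1 is a serine/threonine kinase. Short hairpin RNAs (shRNAs), which direct the degradation of a matching transcript, were expressed from transfected constructs. The cells were kept at confluence for 4 days and then given 50% horse serum for 120 minutes. Each of 4 dual-colour arrays of 60-base probes compared cells carrying 1 hairpin, labelled with Cy3, with cells carrying the scrambled control of that hairpin, labelled with Cy5. MYC was targeted with 2 hairpins and PIM1 with 2 others, so n = 2 for each target and the replicates are different constructs. The labels do not say whether the hairpins of a target were tested in independent experiments. The p-values therefore measure only the spread between these arrays. Differences between hairpins, between cultures and between arrays cannot be told apart in that spread. Between 54.7% and 59.2% of the probe spots were well above background in the shRNA channel. In the scrambled channel the share was 85.8% and 68.4% on the MYC arrays and 65.1% and 60.0% on the PIM1 arrays. After the filter on dim probes, 13787 named genes were measured. Values below are log2 ratios of shRNA over scrambled control, given as the mean ± SD over the 2 arrays of a target, and adjusted p-values are from limma unless another test is named. The number of arrays limits the precision of every value. The dyes were not swapped, so a dye effect of a probe is not separated from an effect of the shRNA within a target.

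The study asked which genes of serum-treated cells depend on MYC and which on PIM1, and the targeted transcripts were examined first. Their levels are not settled by the deposited files, because the columns of these rows disagree with each other, while at nearly all other spots they agree. From the mean signals, which every comparison here uses, the PIM1 probe read -0.79 and -0.71 on the PIM1 arrays (-0.75 ± 0.06, adjusted p = 0.0396). From Feature Extraction's processed signals it read -0.82 and -0.05, and its stored log ratio gave -1.97 and -1.73, beside stored p-values of 0.000169 and 0.791. The MYC probe read -0.04 on the first MYC array from the mean signals and 0 from the processed signals, whereas its stored ratio gave -1.98 beside a stored p-value of 0.976. On the second MYC array it read -0.75 from the mean signals, -2.49 from the processed signals and the stored ratio and 1.00 in the deposited value table, and its signals in both channels equal those of an unnamed probe on the second PIM1 array. The mean-signal values of MYC (-0.39 ± 0.50) did not pass (adjusted p = 0.415). A second MYC probe, whose columns agree, read -0.23 and -0.53 on the MYC arrays. The target transcripts are therefore not used as a check of the array labels, on which all comparisons rest. On the arrays of the other target, where the columns agree, MYC read -0.05 and 1.07 (adjusted p = 0.289) and PIM1 -0.64 and -0.16 (adjusted p = 0.109). The second MYC probe read 0.02 and 0.23 on the PIM1 arrays.

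FOSL1, a member of the FOS family of transcription factors that is induced by serum, showed the same kind of disagreement on all 4 arrays. Its mean signals gave -1.31 ± 0.63 with MYC shRNA (adjusted p = 0.0317) and -1.57 ± 0.21 with PIM1 shRNA (adjusted p = 0.0347). The processed signals of the same spots gave -0.39, -0.72, -0.06 and -0.50, and the stored ratios -1.26, -1.39, -2.28 and -1.91, beside stored p-values from 0.129 to 0.919. The shRNA channel was well above background on 0 of 4 arrays and the scrambled channel on 3. A second FOSL1 probe read 0.01, -0.03, 0.05 and 0.05 from the mean signals, with stored ratios from -1.96 to -1.32. No direction or fold of FOSL1 is drawn from these values. ID2, an inhibitor of helix-loop-helix transcription factors, read -0.06 ± 0.53 with MYC shRNA and -0.65 ± 0.39 with PIM1 shRNA on a probe whose columns agree and did not pass for either (adjusted p = 0.879 and 0.109). A second ID2 probe read -1.39 and -1.01 on the MYC arrays, and on both PIM1 arrays its signals equal those of other probes on the first MYC array, so that it gives no value there. In the array's coordinates (hg17), the MYC probe lies on chromosome 8 at 128822450 to 128822509, the PIM1 probe on chromosome 6 at 37251080 to 37251139, the FOSL1 probe on chromosome 11 at 65416674 to 65416733 and the ID2 probe of the first values on chromosome 2 at 8774880 to 8774939. No annotation of exons was used for this build.

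**Figure D1:**
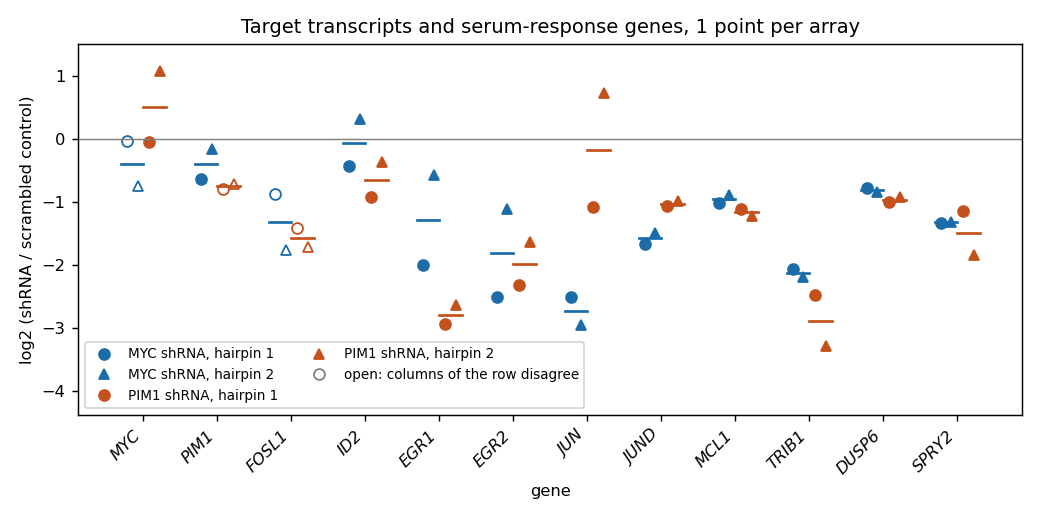
Log2 ratio of shRNA over scrambled control (vertical axis) for the targeted transcripts and 10 further genes, with 1 point per array (circles, hairpin 1, triangles, hairpin 2) and bars for the mean of the 2 arrays of each target. Open points mark spots whose columns disagree, among them all 4 of FOSL1 and those of MYC and PIM1 on the arrays of their own hairpins. MCL1, JUND, TRIB1, DUSP6 and SPRY2 lie below 0 on all 4 arrays, while JUN lies at 0.74 with the second PIM1 hairpin.

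The first comparison set MYC shRNA against its scrambled controls. Serum immediate-early genes, which are transcribed within minutes of serum addition, were lower. Of 38 measured members 11 fell and 0 rose (16 fell when adjusted over the list alone), with a median of -0.525. The transcription factor JUND fell (-1.58 ± 0.13, adjusted p = 0.0104), as did the survival factor MCL1 (-0.95 ± 0.08, adjusted p = 0.0191), the pseudokinase TRIB1 (-2.12 ± 0.09, adjusted p = 0.0198) and the transcription factors EGR2 (-1.81 ± 0.99, adjusted p = 0.0394) and JUN (-2.74 ± 0.32, adjusted p = 0.0274). The list passed a camera test with a preset correlation (adjusted p = 4.29e-06). It did not pass camera with an estimated correlation (adjusted p = 0.654) or fry (adjusted p = 0.13). A second TRIB1 probe, on the same arrays, gave 0.02. Over all 4 arrays the mean of 2 other MCL1 probes was -0.22, against -1.06 for the probe used, and JUND, EGR2 and JUN had no other kept probe. FOSL1 is 1 of the 11, and without the spots whose columns disagree the median was -0.515 (adjusted p = 8.43e-06).

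Cytosolic ribosomal proteins were higher on the MYC shRNA arrays after loess, with 8 of 34 members higher, 0 lower (9 and 1 when adjusted over the list alone) and a median of 0.303, which turned to -0.973 with median centring in place of loess. With processed signals the median was 0.167 and did not pass (adjusted p = 0.17), nor did it from the deposited value table (0.191, adjusted p = 0.172). Over all genes whose symbols begin with RPL, a grouping chosen after the data had been seen, the median was 0.02 (52 genes, 6 higher and 3 lower, adjusted p = 0.536), and for RPS it was 0.10 (42 genes, 7 and 3, adjusted p = 0.378). RPL11 (0.94 ± 0.02, adjusted p = 0.0174) and RPS2 (0.90 ± 0.15, adjusted p = 0.0231) rose. Their probes can also bind processed copies of these genes, which makes the gene assignment uncertain. The list's camera adjusted p was 0.000163 (adjusted p = 0.654 with an estimated correlation). Genes of cholesterol synthesis had a median of 0.285 (-0.583 with median centring), with 2 of 23 higher and 1 lower (8 and 2 when adjusted over the list alone), among them the sterol oxidase MSMO1 (1.01 ± 0.17, adjusted p = 0.0222), the isomerase IDI1 (0.70 ± 0.39, adjusted p = 0.0474) and, in the other direction, the lanosterol synthase LSS (-0.40 ± 0.01, adjusted p = 0.0382). The camera adjusted p was 0.0208 (adjusted p = 0.654 with an estimated correlation). G2/M and mitosis genes had a median of 0.198 (-0.604 with median centring), with 2 of 30 higher and 2 lower, for example the checkpoint kinase BUB1B (0.91 ± 0.06, adjusted p = 0.0198), the ubiquitin-conjugating enzyme UBE2C (-0.60 ± 0.16, adjusted p = 0.0273) and the centromeric histone CENPA (-0.78 ± 0.12, adjusted p = 0.0301). Their camera adjusted p was 0.0333 (adjusted p = 0.936 with an estimated correlation). Median centring moved the median of all genes to -0.45, and RPL11, RPS2 and IDI1 then read -0.337, -0.406 and -0.258. Without the second MYC array the medians of cholesterol synthesis and G2/M were 0.197 and 0.086 and did not pass (adjusted p = 0.0636 and 0.628). Both calls were also lost with the strict filter on dim probes (adjusted p = 0.0521 and 0.0828) and from the deposited value table (0.052 for both). The G2/M call was further lost without the dim filter (0.0611) and with the GC trend removed (0.126).

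Histone genes fell on the MYC shRNA arrays, with 9 of 23 lower and 0 higher (12 lower when adjusted over the list alone) and a median of -0.388. The list passed camera (adjusted p = 0.00304) and not with an estimated correlation (adjusted p = 0.654). H3C4 read -0.52 ± 0.12 (adjusted p = 0.0303) and H2BC5 read -1.40 ± 0.74 (adjusted p = 0.0331). The H4 genes H4C3 (-2.52 ± 1.29, adjusted p = 0.0348), H4C2 (-2.44 ± 1.30, adjusted p = 0.037) and H4C13 (-2.36 ± 1.22, adjusted p = 0.0359) are near-identical copies whose probes cannot be taken as separate measurements. Markers of blood cells, a cell type foreign to this line, had a median of -0.359 with 1 of 9 lower, CD3E (-0.45 ± 0.05, adjusted p = 0.0336), and a camera adjusted p of 0.0401 (adjusted p = 0.654 with an estimated correlation). Without the second MYC array it was -0.180 (adjusted p = 0.0778), and without either PIM1 array the call was lost at an adjusted p of 0.0712. It was also lost without the filter on dim probes (-0.151, adjusted p = 0.0846), at a normexp offset of 16 (adjusted p = 0.0567), with median centring (adjusted p = 0.254) and with the GC trend removed (adjusted p = 0.135).

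The other 22 lists did not pass camera with MYC shRNA. Of 29 MYC-activated targets 0 were higher and 1 was lower, the methionine adenosyltransferase MAT2A (-1.04 ± 0.43, adjusted p = 0.0355), with a list adjusted p of 0.976. Of 19 MYC-repressed targets 2 were higher and 5 lower (adjusted p = 0.989), with TXNIP at 0.72 ± 0.08 (adjusted p = 0.0222) and the growth-arrest gene GADD45B at -1.16 ± 0.08 (adjusted p = 0.0182). In the MYC/MAX/MXD network 1 of 20 was higher and 2 were lower (adjusted p = 0.963), including MYCN (-0.91 ± 0.32, adjusted p = 0.025), whose probe holds 40% cytosine. PIM kinases and substrates had 1 higher and 3 lower of 19 (adjusted p = 0.9), among them the cell-cycle inhibitor CDKN1B (0.56 ± 0.07, adjusted p = 0.025). The list on H3 serine 10 phosphorylation and elongation had 1 higher and 4 lower of 20 (adjusted p = 0.963), and 3 of the latter act on the elongation factor P-TEFb or on elongation itself, namely LARP7 (-1.27 ± 0.10, adjusted p = 0.0135), ELL2 (-1.08 ± 0.16, adjusted p = 0.0188) and HEXIM1 (-0.85 ± 0.36, adjusted p = 0.0292). Ribosome biogenesis had 0 higher and 2 lower of 30 (adjusted p = 0.305), translation initiation 3 and 3 of 25 (adjusted p = 0.976), nucleotide synthesis 4 and 0 of 24 (adjusted p = 0.0916) and G1/S and DNA replication 2 and 1 of 30 (adjusted p = 0.198). Examples are the initiation factor EIF3A (-1.33 ± 0.05, adjusted p = 0.0135), the purine enzyme GART (0.74 ± 0.08, adjusted p = 0.0222) and the replication helicase subunit MCM6 (0.65 ± 0.06, adjusted p = 0.0235). ERK feedback and delayed-early genes had 1 higher and 4 lower of 22 (adjusted p = 0.198), with the ERK phosphatase DUSP6 at -0.81 ± 0.05 (adjusted p = 0.0214) and SPRY2, an inhibitor of receptor signalling, at -1.33 ± 0.01 (adjusted p = 0.0239). SRF/MRTF and YAP/TEAD targets had 1 and 2 of 21 (adjusted p = 0.963). With median centring TXNIP read -0.099, CDKN1B -0.113, GART -0.184 and MCM6 -0.361.

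Among stress and metabolism lists on the MYC arrays, p53 targets had 0 higher and 5 lower of 24 (adjusted p = 0.198), including the BH3-only gene PMAIP1 (-1.81 ± 0.03, adjusted p = 0.00816). The rotation test fry, which asks whether a list moves to one side, passed for p53 targets (adjusted p = 0.0379) and for the RNA interference machinery (adjusted p = 0.0288), where 0 were higher and 5 lower of 14, with AGO3 at -1.07 ± 0.15 (adjusted p = 0.0217) and camera at an adjusted p of 0.672. Interferon-stimulated genes had 1 and 3 of 26 (adjusted p = 0.963), the unfolded protein and integrated stress response 1 and 4 of 26 (adjusted p = 0.344) and heat shock proteins 1 and 1 of 19 (adjusted p = 0.976). Glycolysis and hypoxia had 1 and 3 of 27 (adjusted p = 0.606), oxidative phosphorylation 4 and 4 of 32 (adjusted p = 0.963) and apoptosis regulators 1 and 6 of 25 (adjusted p = 0.963). Of the markers of other cell types, fibroblast genes had 0 and 1 of 9 (adjusted p = 0.806), neuronal genes 1 and 2 of 12 (adjusted p = 0.198) and epithelial genes 1 and 0 of 11 (adjusted p = 0.792). The median and the mean differed in sign for glycolysis and hypoxia (0.088 and -0.086), oxidative phosphorylation (0.033 and -0.047) and apoptosis regulators (0.011 and -0.227). The median and mean of MYC-activated targets (-0.046 and -0.045) lay below 0. So did those of the MYC/MAX/MXD network (-0.004 and -0.084) and of translation initiation (-0.039 and -0.060). Camera, which compares the test statistics of a list with those of all other genes, gave the direction of these lists as up.

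Across all genes, 1706 of 13785 passed with MYC shRNA, 685 higher and 1021 lower (4617 at an unadjusted p under 0.05), and 14 higher and 292 lower changed by at least 2-fold. The genes named by size of change were DECR1, a mitochondrial beta-oxidation enzyme (2.46 ± 0.06, 5.52-fold, adjusted p = 0.00816), the elongation factor EEF1A1 (1.59 ± 0.09), CTNNB1, which encodes beta-catenin (1.53 ± 0.35), RBBP8NL (1.31 ± 0.17), PRPS2 (1.27 ± 0.25), the peroxidase PRDX3 (1.25 ± 0.32), the splicing factor SRSF1 (1.19 ± 0.06) and ARHGEF26 (1.16 ± 0.01). At the other end were the nuclear noncoding RNA MALAT1 (-3.34 ± 0.26, 10.1-fold lower, adjusted p = 0.0135), SOX3 (-2.78 ± 1.00), JUN, SLC26A1 (-2.58 ± 0.99), the chaperone HSP90AA1 (-2.55 ± 0.03) and the H4 genes. Other probes of EEF1A1 (1.72, 1.75 and 2.18) and SRSF1 (0.89) were also higher. Other probes read 0.01 for DECR1, 0.22 for CTNNB1, 0.31 for PRPS2, -0.16 for PRDX3, -0.38 for ARHGEF26, -0.01 for SOX3 and 0.10 for SLC26A1, while they read 0.13, -1.32 and 0.23 for MALAT1 and -0.79, 0.71 and -0.67 for HSP90AA1. Copies of EEF1A1 and HSP90AA1 elsewhere in the genome leave their gene assignment uncertain. With PIM1 shRNA, SOX3 and SLC26A1 read the other way, at 2.33 ± 1.33 and 2.24 ± 1.47, and did not pass (adjusted p = 0.0543 and 0.062). The SOX3 probe holds 43.3% cytosine and that of SLC26A1 33.3%. Under the size rule, 154 genes were at least 1.5-fold higher and 598 lower with both MYC hairpins, against 4 in opposite directions (4 and 4139 with median centring, 929 and 1449 with processed signals). The limma count of 1706 became 0 without the first MYC array (2700 at an unadjusted p under 0.05), 0 without the second (2135) and 2627 without either PIM1 array. Median centring gave 49 higher and 5712 lower.

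The second comparison set PIM1 shRNA against its scrambled controls. Serum immediate-early genes were again lower, with 9 of 38 lower, 0 higher (12 lower when adjusted over the list alone) and a median of -0.317. TRIB1 (-2.89 ± 0.57), MCL1 (-1.17 ± 0.08) and JUND (-1.03 ± 0.06) fell, each at an adjusted p of 0.0347, as did the zinc-finger transcription factors EGR1 (-2.79 ± 0.21, 6.91-fold, adjusted p = 0.0347) and EGR2 (-1.98 ± 0.49, adjusted p = 0.0402). EGR1 did not pass with MYC shRNA (-1.29 ± 1.00, adjusted p = 0.0661), and its difference between the targets did not pass either (adjusted p = 0.204). FOSL1 is 1 of the 9 genes that passed. The list passed camera (adjusted p = 0.00019), also without the spots whose columns disagree (median -0.301, adjusted p = 0.000484). It did not pass camera with an estimated correlation (adjusted p = 0.846) or fry (adjusted p = 0.295). Without the first PIM1 array its median was -0.123 (adjusted p = 0.516), and without the second it was -0.633 (adjusted p = 1.84e-12).

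No other list passed with PIM1 shRNA, with camera adjusted p between 0.177 and 0.999. Ribosomal proteins had 6 higher and 2 lower of 34 (adjusted p = 0.177), with RPL5 at 0.74 ± 0.06 and RPLP0 at 0.91 ± 0.24, both at an adjusted p of 0.0347 (-0.349 and -0.201 with median centring). Glycolysis and hypoxia genes had 6 higher and 3 lower of 27 (adjusted p = 0.177), among them the enolases ENO1 (1.25 ± 0.46) and ENO2 (0.91 ± 0.03) and, in the other direction, the peptide hormone ADM (-1.12 ± 0.14), each at an adjusted p of 0.0347. The MYC/MAX/MXD network had 4 higher and 1 lower of 20 (adjusted p = 0.201), the latter being FBXW7, the ubiquitin ligase subunit that targets MYC (-1.39 ± 0.63, adjusted p = 0.039). In the elongation list 2 were higher and 3 lower of 20 (adjusted p = 0.4), including ELL2 (-1.24 ± 0.07) and HEXIM1 (-1.25 ± 0.05), both at 0.0347. Its median was 0.235 and its mean 0.023. MYC-activated targets had 3 higher and 3 lower of 29 (adjusted p = 0.903), with the translation factor BZW2 at -0.74 ± 0.05 and the nucleolar protein NPM1 at -0.58 ± 0.20 (adjusted p = 0.0347 and 0.038), and MYC-repressed targets 1 and 2 of 19 (adjusted p = 0.844). Of the unfolded protein and integrated stress response 1 was higher and 6 were lower of 26 (adjusted p = 0.3), including CEBPG (-1.52 ± 0.02), asparagine synthetase ASNS (-0.68 ± 0.05) and its regulator ATF4 (-0.60 ± 0.07), each at an adjusted p of 0.0347. The mean over all probes of a gene gave 0.252 for NPM1 and 0.021 for ATF4. Histone genes had 0 higher and 0 lower of 23 (adjusted p = 0.844), and RNA interference genes 1 and 0 of 14 (adjusted p = 0.999). ERK feedback genes had 0 and 2 of 22 (adjusted p = 0.86), DUSP6 (-0.96 ± 0.06) and SPRY2 (-1.49 ± 0.50). The markers of fibroblast, blood, neuronal and epithelial cells had adjusted p of 0.844, 0.999, 0.418 and 0.903.

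Of the remaining lists on the PIM1 arrays, PIM kinases and substrates had 0 higher and 1 lower of 19 (adjusted p = 0.86), ribosome biogenesis 1 and 3 of 30, translation initiation 2 and 2 of 25 and nucleotide synthesis 3 and 0 of 24 (adjusted p = 0.4 for each of these 3). G1/S and DNA replication had 2 and 0 of 30 (adjusted p = 0.348), G2/M and mitosis 3 and 3 of 30 (adjusted p = 0.86), cholesterol synthesis 2 and 1 of 23 (adjusted p = 0.201) and oxidative phosphorylation 3 and 7 of 32 (adjusted p = 0.999). SRF/MRTF and YAP/TEAD targets had 1 and 1 of 21 (adjusted p = 0.918), p53 targets 1 and 5 of 24 (adjusted p = 0.3), interferon-stimulated genes 0 and 2 of 26 (adjusted p = 0.999), heat shock proteins 2 and 4 of 19 (adjusted p = 0.491) and apoptosis regulators 1 and 2 of 25 (adjusted p = 0.844). The median and the mean differed in sign for PIM kinases (0.032 and -0.008), SRF/MRTF targets (0.023 and -0.012), interferon-stimulated genes (0.037 and -0.028) and fibroblast markers (-0.022 and 0.042). Camera gave up for RNA interference genes (median -0.010, mean -0.053) and blood markers (-0.016 and -0.008), and fry gave down for MYC-repressed targets (0.022 and 0.057).

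Across all genes, 1466 of 13787 passed with PIM1 shRNA, 635 higher and 831 lower (4861 at an unadjusted p under 0.05), and 125 higher and 128 lower changed by at least 2-fold. The genes named for their rise were HS2ST1, a heparan sulfate sulfotransferase (2.58 ± 1.12), CMIP (2.45 ± 1.19), IFITM5 (2.38 ± 1.21), the CREB coactivator CRTC1 (2.36 ± 0.91), the BH3-only gene BBC3 (2.24 ± 0.87), the ligand WNT6 (2.22 ± 0.91) and the homeobox gene LBX1 (2.19 ± 0.92), with adjusted p from 0.0363 to 0.0432. The probes of HS2ST1, IFITM5, CRTC1, BBC3 and WNT6 hold 40% to 51.7% cytosine, against a median of 21.7% over all genes tested. Other probes on the PIM1 arrays gave 0.05 for CMIP, 0.09 for WNT6, 0.03 and -1.05 for BBC3 and 0.17, -1.07 and -0.92 for HS2ST1. Beside TRIB1, EGR1 and EGR2, the genes named for their fall were the deubiquitinase OTUD1 (-2.22 ± 0.30), ZNF550 (-2.09 ± 1.09), the O-GlcNAc transferase OGT (-2.02 ± 1.03), the spindle protein CKAP2 (-1.95 ± 0.85) and SCAF8 (-1.90 ± 1.17), with adjusted p from 0.0347 to 0.0447. Their other probes gave -0.15 for OTUD1, -0.12 for OGT, 0.28 for CKAP2 and 0.10 for SCAF8, and -0.14 for TRIB1. Under the size rule 265 genes were at least 1.5-fold higher and 400 lower with both PIM1 hairpins, against 5 in opposite directions (7 and 2319 with median centring, 1086 and 1319 with processed signals). The limma count of 1466 became 0 without the second PIM1 array (2741 at an unadjusted p under 0.05), 0 without either MYC array (4093 in both cases) and 2385 without the first PIM1 array. Median centring gave 16 higher and 2583 lower, and moved the median of all genes to -0.21.

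**Figure D2:**
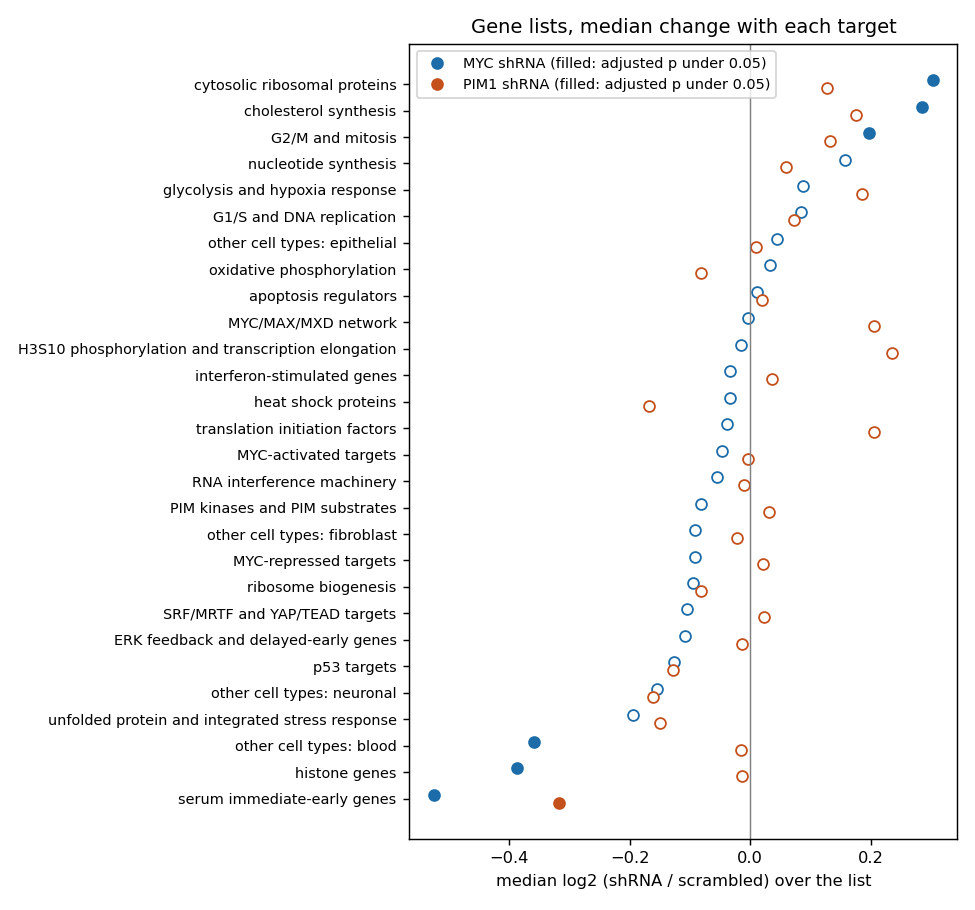
Median log2 ratio (horizontal axis) over the measured genes of each of 28 lists, for MYC shRNA (blue) and PIM1 shRNA (orange). Filled points passed camera at a preset correlation. Serum immediate-early genes lie lowest for both targets, at -0.525 and -0.317, and under median centring the medians of ribosomal proteins, cholesterol synthesis and G2/M with MYC shRNA turn to -0.973, -0.583 and -0.604.

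The third comparison tested the difference between the targets, as MYC minus PIM1. A probe's dye effect that is common to all arrays cancels in it. DECR1 was 2.36 ± 0.12 (standard error) higher with MYC shRNA than with PIM1 shRNA (adjusted p = 0.0373). In total 5 genes passed on that side, among them RBBP8NL (1.37 ± 0.13), the guanine nucleotide exchange factor ARHGEF26 (1.11 ± 0.11) and the calpain inhibitor CAST (0.83 ± 0.11), with adjusted p up to 0.0452. The other DECR1 probe read 0.01 and -0.12 with MYC and PIM1 shRNA, and that of ARHGEF26 read -0.38 and -0.67. For CAST the other probe read -0.06 and 0.19, which is the other direction. NEMP1 (1.97 ± 0.57), CDC42SE1 (1.29 ± 0.22) and NUDT4 (1.40 ± 0.30) followed by size and did not pass (adjusted p = 0.195, 0.0828 and 0.129).

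On the other side 219 genes were lower with MYC than with PIM1 shRNA. The calls were less one-sided without the first PIM1 array, a fit that leaves a lone PIM1 array. The named ones were HS2ST1 (-4.63 ± 0.62), WNT6 (-4.38 ± 0.56), PRR7 (-4.23 ± 0.46), the polarity protein PARD6G (-4.20 ± 0.57), CRTC1 (-4.17 ± 0.56), BBC3 (-4.13 ± 0.50) and LBX1 (-4.07 ± 0.50), with adjusted p from 0.0373 to 0.0473. Each of these except LBX1 has a probe of at least 40% cytosine, and the other probes of PRR7 (-0.08 and -0.32 with MYC shRNA, 0.06 and 0.31 with PIM1 shRNA) and PARD6G (-0.05 and -0.03) lay near 0. The heat shock protein HSP90AA1 (-1.46 ± 0.16, adjusted p = 0.0373), MALAT1 (-2.43 ± 0.34, adjusted p = 0.0493) and the P-TEFb regulator LARP7 (-0.90 ± 0.12, adjusted p = 0.0463) also passed on this side. With MYC and PIM1 shRNA, other HSP90AA1 probes read -0.79 and -0.08, 0.71 and 0.11, and -0.67 and -0.12. Other MALAT1 probes read 0.13 and 0.03, -1.32 and -0.42, and 0.23 and 0.40. Of 28 lists, histone genes passed camera, with a median difference of -0.242 and 20 of 23 members below 0 (adjusted p = 0.0253, adjusted p = 0.964 with an estimated correlation), although 0 members passed alone. The call was lost without the first MYC array (-0.183, adjusted p = 0.093) and without the second PIM1 array (-0.110, adjusted p = 0.14), with scaling between arrays (adjusted p = 0.0667), with the strict filter (0.159), with the mean over all probes of a gene (0.0845) and with the GC trend removed (0.108). For the other lists the camera adjusted p lay between 0.213 and 0.928, and for serum immediate-early genes it was 0.689. The median and the mean of the difference differed in sign for MYC-activated targets, SRF/MRTF targets, G1/S, p53 targets, heat shock, oxidative phosphorylation, apoptosis and epithelial markers, and for interferon-stimulated genes camera gave up with both below 0 (-0.012 and -0.033). In total 224 genes passed (2794 at an unadjusted p under 0.05), 117 of them with probes of at least 40% cytosine, all lower with MYC shRNA. Of all genes tested 1.9% had such a probe. Without those probes 3 genes passed, DECR1, ANKDD1A and SYNCRIP, the last pair named after their values were seen. The other 107 calls then kept the same probes and differences (median size 1.57, with a median standard error of 0.176 before and 0.175 after), and their adjusted p then lay between 0.0369 and 0.0912. Most of their calls were lost through the adjustment for multiple testing, since the unadjusted p of all 107 became lower. The limma count became 0 without the filter on dim probes (3143 at an unadjusted p under 0.05), 0 without the second array of either target (994 for MYC and 1483 for PIM1), 77 without the first MYC array and 1396 without the first PIM1 array.

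**Figure D3:**
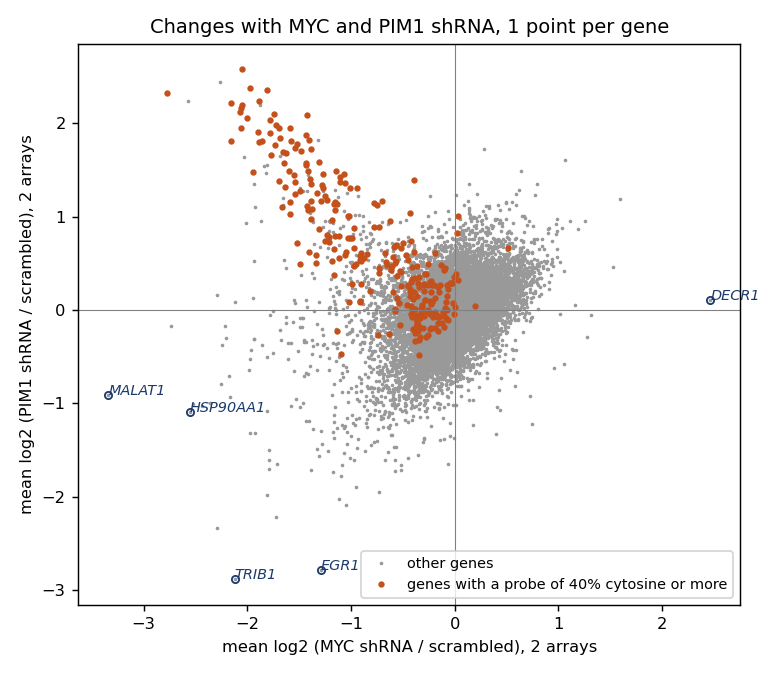
Mean log2 ratio with MYC shRNA (horizontal axis, 2 arrays) against that with PIM1 shRNA (vertical axis, 2 arrays), with 1 point per gene and orange for genes with a probe of at least 40% cytosine. These genes extend to the upper left, where 149 genes were lower with MYC shRNA and higher with PIM1 shRNA, while TRIB1 and EGR1 lie at the lower left.

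The fourth comparison asked which genes changed with both targets. Of 13785 genes, 178 rose with both (31.6 expected for independent lists) and 254 fell with both (61.5 expected), together 25.3% of the genes called with MYC shRNA. With median centring in place of loess 0 rose and 2391 fell with both. The targets had their own controls but the same dye orientation. Both contrasts also share the spread estimate of each gene, which favours the same genes in both lists. The expected counts for independent lists are therefore not what an absence of shared changes would give. TRIB1, MCL1, JUND and EGR2 fell with both, as did GADD45B (-1.37 ± 0.18 with PIM1 shRNA), ELL2, HEXIM1, DUSP6 and SPRY2. EEF1A1 (1.19 ± 0.07 with PIM1 shRNA), PRDX3 (0.95 ± 0.12), SRSF1 (0.87 ± 0.07), BUB1B (0.88 ± 0.11) and GART (0.62 ± 0.08, -0.010 with median centring) rose with both. Other probes of EEF1A1 and SRSF1 were also higher with both, while the other PRDX3 probe read -0.16 with MYC and -0.18 with PIM1 shRNA. Among genes called in opposite directions, 149 were lower with MYC and higher with PIM1 shRNA (47 expected), while 0 were higher with MYC and lower with PIM1 shRNA (41.2 expected). The 149 became 11 with median centring, where only 16 genes were called higher with PIM1 shRNA, and 78 without the filter on dim probes. The 149 include HS2ST1, CMIP, CRTC1, BBC3, WNT6, LBX1, PRR7 and PARD6G. Also among them are the glycolytic enzyme gene ALDOA (-1.43 ± 0.47 and 1.55 ± 0.68) and CEBPA (-1.63 ± 0.60 and 1.68 ± 0.76). Of the 149, 99 (66.4%), ALDOA and CEBPA among them, have a probe of at least 40% cytosine, against 1.9% of all genes tested. Under the size rule 24 genes were at least 1.5-fold higher and 121 lower on all 4 arrays, which became 0 and 1603 with median centring and 278 and 415 with processed signals. The 432 calls in the same direction became 0 without either MYC array or without the second PIM1 array, because the count of a target was then 0 itself.

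The agreement of the arrays was compared across genes, which are not independent replicates, for the 6 pairs of arrays. Pearson's r was 0.796 between the MYC hairpins (Spearman's rho 0.727) and 0.753 between the PIM1 hairpins (rho 0.71). Between hairpins of different targets r was 0.46, 0.183, 0.207 and 0.007, with rho of 0.585, 0.307, 0.361 and 0.149.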

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

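The tests of GC content and of the scrambled channels were written before their results were seen. The test of other probes was chosen after the result was seen, as were the test of a transcript response, the test of the size kept after GC removal, the condition on bright other probes and the condition on what the GC smoother leaves behind.

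The test of the difference between the targets picked out 224 genes, of which 219 were lower with MYC than with PIM1 shRNA. This split was less one-sided without the first PIM1 array, a fit that leaves a lone PIM1 array. Called lower with MYC and higher with PIM1 shRNA were 149 genes (11 with median centring and 78 without the dim filter). Removing the GC trend left 136 such genes, 116 of them the same. The bound set beforehand for GC content, fewer than 0.5 times as many genes, was not met. The median difference of the 149 moved from -2.46 to -1.94, 0.79 times as much (0.75 to 0.85). This argues against the smooth GC trend as the whole cause. The smoother still left -0.47 of -1.18 at the 199 probes of at least 70% GC. The bound was therefore unsuitable for base composition in any other form, which stays open. Other probes of 75 of these genes showed a median difference 0.04 times that of the probes used (0.02 to 0.06 by bootstrap), and 2 of the 75 differed at least 0.5 times as much, which is consistent with a signal of the single probe and not of the transcript, but over the 21 genes with bright other probes the ratio was 0.13 (0.03 to 0.27), and its upper end, above the 0.25 set as the bound, keeps this open. That ratio lies below 0.5 and argues against a real opposite response of the transcripts to MYC and PIM1 shRNA for these 21 genes as a set (2 of them differed at least 0.5 times as much), while for the 128 others this biological explanation stays open. The genes were picked by the probes used, which also lowers such ratios, by an amount that was not computed. A median share of 0.49 of the difference (0.48 to 0.50) lay in the scrambled channels and the rest in the shRNA channels. A difference of the scrambled controls alone needed at least 0.75, and a share under 0.25 would have spoken against it. The scrambled medians were 9.99 and 10.47 (log2) on the MYC arrays and 9.56 and 8.53 on the PIM1 arrays. The shRNA medians were 8.92 and 8.93 against 10.49 and 9.96. The share argues against the controls alone, and against the hairpins alone, as the whole cause. Each may hold part of the difference, and a signal of the single probe stays open too.

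The shift of histone genes differed between the targets, with a median difference of -0.242 (camera adjusted p = 0.0253). It did not pass with an estimated correlation (adjusted p = 0.964) or fry (adjusted p = 0.555), and the call was lost with scaling between arrays (adjusted p = 0.0667), with the strict filter on dim probes (0.159), with the mean over all probes of a gene (0.0845) and with the GC trend removed (0.108). It was also lost without the first MYC array (-0.183, adjusted p = 0.093) and without the second PIM1 array (-0.110, adjusted p = 0.14). Probes without a gene name had no part in the comparisons of genes and lists, and of these probes tested on their own 1907 of 8448 passed with MYC shRNA, 1482 of 8450 with PIM1 shRNA and 217 of 8448 for the difference.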

How the results depend on the processing

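Over all alternatives, 76 of 108 values of the 6 lists called with MYC shRNA kept their direction and call, 29 lost the call and 3 reversed, and for called genes fixed beforehand or named by size 204 of 254 values with MYC shRNA, 187 of 269 with PIM1 shRNA and 125 of 194 for the difference kept theirs, while the others lost the call and 0 reversed. Of the further named genes past the threshold, 554 of 705 values, 458 of 615 and 70 of 120 kept theirs, 143, 150 and 50 lost the call and 8, 7 and 0 reversed. Unless stated, the cause was not tested. Signal over background limits dim genes, since 54.7% to 59.2% of spots were well above background in the shRNA channel. Leaving out 1 array leaves a target with a lone array, which is assumed to vary like the other group.

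Leaving out an array gave 0 to 2627 genes for MYC shRNA, 0 to 2385 for PIM1 shRNA, 0 to 1396 for the difference and 0 to 582 for both in the same direction. Lists ranged over 3 to 7 for MYC shRNA, 0 to 2 for PIM1 shRNA and 0 to 5 for the difference. The count was 0 for MYC shRNA without either MYC array, for PIM1 shRNA without either MYC array or the second PIM1 array, and for the difference without the second array of either target. Lists numbered 3 for MYC shRNA without the second MYC array, 0 for PIM1 shRNA without the first PIM1 array and 2 without the second, and 5 for the difference without the second MYC array and 0 without the second PIM1 array. Genes changed by MYC shRNA numbered 5761 with median centring, 2873 with trend and robust fitting, 142 with TREAT, 3448 at an adjusted p under 0.1, 2627 with its own arrays alone and 2791 with the separate-channel fit. For PIM1 shRNA they numbered 2473 with processed signals, 2904 at offset 16, 2599 with median centring, 2381 with scaling, 908 without the dim filter, 2513 from the value table, 3005 with trend and robust fitting, 0 with TREAT (1825 at an unadjusted p under 0.05), 3747 at an adjusted p under 0.1, 0 with its own arrays alone (4093 at an unadjusted p under 0.05) and 3001 with separate channels. For the difference they numbered 406 at offset 16, 0 without the dim filter, 489 with trend and robust fitting, 132 with TREAT, 414 at an adjusted p under 0.1 and 478 with separate channels. For both targets in the same direction they numbered 749 at offset 16, 2391 with median centring, 888 with trend and robust fitting, 0 with TREAT, 1265 at an adjusted p under 0.1 and 914 with separate channels.

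Of the alternatives chosen after the data were seen, testing all probes gave 4511, 3267 and 416 genes for MYC, PIM1 and the difference (more probes tested). Leaving out cytosine-rich probes gave 1542 and 1374 genes for MYC and PIM1, and 3 for the difference, where the other 107 calls kept their differences and most lost the call through the adjustment alone. Leaving out the 82 spots whose columns disagree gave 1735, 1489 and 234 genes, 447 for both in the same direction, and 6, 1 and 1 lists, so the counts over all genes do not rest on them. It left no value for the PIM1 transcript with PIM1 shRNA or for the MYC transcript with MYC shRNA on the probes used.

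Genes of at least 1.5-fold with both MYC hairpins numbered 2378 with processed signals, 1149 at offset 16, 4143 with median centring, 2386 from the value table and 226 at 2-fold. With both PIM1 hairpins they numbered 2405, 1035, 2326, 427 with the mean of probes, 2426 from the table and 139 at 2-fold, and with all 4 hairpins 693, 240, 1603, 92, 704 and 24. The mean correlation of arrays of different targets was 0.503 with median centring. MYC's own transcript was -1.064 with median centring (adjusted p = 0.0342) and ranged from -1.243 to -0.365 (adjusted p from 0.0342 to 0.641). Median centring moved the median of all genes with MYC shRNA to -0.45. The MYC values also rest on spots whose columns disagree, so no knockdown is drawn from them. PIM1's own transcript was -0.438 with processed signals (adjusted p = 0.235) and -0.751 without the dim filter (adjusted p = 0.0509), and ranged from -1.851 to -0.438 (adjusted p from 0.0154 to 0.235). The ends of the PIM1 range come from the stored ratio and the processed signals of the same spots, which disagree.

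Lists past the threshold for MYC shRNA numbered 3 from the value table, 0 with an estimated correlation and 2 with fry. Those 2 were p53 targets and the RNA interference machinery, and none of the 6 lists called with camera passed fry. For PIM1 shRNA they numbered 7 with median centring, 0 with an estimated correlation and 0 with fry. For the difference they numbered 0 with scaling, 0 with the strict filter, 0 with the mean of probes, 0 with the GC trend removed, 0 with an estimated correlation and 0 with fry. With median centring the medians with MYC shRNA reversed to -0.973 for ribosomal proteins, -0.604 for G2/M and -0.583 for cholesterol synthesis. Among named genes it reversed CDKN1B (-0.113), GART (-0.184), IDI1 (-0.258), MCM6 (-0.361), RPL11 (-0.337), RPL5 (-0.841), RPS2 (-0.406) and TXNIP (-0.099) with MYC shRNA and GART (-0.010), RPL11 (-0.605), RPL5 (-0.349), RPLP0 (-0.201) and RPS2 (-0.378) with PIM1 shRNA. The mean over all probes of a gene reversed ATF4 (0.021) and NPM1 (0.252) with PIM1 shRNA. Median centring moved the median of all genes to -0.09 for the difference.

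With the hairpin number as a replicate block, 0 genes passed for the difference (2472 at an unadjusted p under 0.05), and the histone list's call stayed. Same-numbered hairpins' deviations from the target mean correlated at r = -0.077 across genes, which does not pair the arrays. The slide or scan date as a block was not run, because each array has its own slide.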

Other observations

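Families of genes were formed by the letters that begin the symbol, with at least 8 members, and 241 families were tested with camera after the data had been seen. Nucleoporins (NUP) had a median of 0.26 with MYC shRNA over 23 genes, 3 of them higher and 0 lower (adjusted p = 0.011), and subunits of the chaperonin CCT had a median of 0.34 over 8 genes, with 3 higher (adjusted p = 0.0204). Neither passed with an estimated correlation (adjusted p = 0.95 for both), and under median centring the medians were -0.49 and -0.66. Olfactory receptors (OR), which this line is not known to use, had a median of -0.16 over 76 genes with each target (adjusted p = 0.011 and 0.018), 0 of them higher and 1 and 2 lower. With an estimated correlation the adjusted p was 0.95 and 0.986. Under median centring it was -0.07 and -0.14, above the median of all genes there (-0.45 and -0.21).

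The tests of other probes in the paragraphs that follow were chosen after the results were seen, as were the limit of 40% cytosine and the hypothesis about it. The tests of GC content were not. In total 432 genes changed the same way with both targets. The bound set beforehand for GC content was fewer than 0.5 times as many calls after removal of its trend. It was not met, since 644 genes were called then, 417 of the 432 among them. A count that rises also depends on the spread and the adjustment, and the size kept was not computed for these genes. The smoother also left -0.47 of a median MYC minus PIM1 difference of -1.18 at probes of at least 70% GC. Base composition therefore stays open for these genes. Other probes of 191 of these genes changed 0.19 times as much (0.14 to 0.23) and had the same sign in 70.7% of cases. The genes were picked by the probe used, the brightest of each gene, so a lowered ratio would arise without dye bias as well. Dye bias or cross-hybridization of the single probe may explain part of the pattern, but this ratio alone does not show it. Over the 57 genes with bright other probes the ratio was 0.41 (0.21 to 0.60), at 0.63 (0.30 to 0.93) for 19 genes higher in both and 0.25 (0.08 to 0.55) for 38 lower in both, so dye bias and an effect of the shRNAs cannot be told apart for these genes. That both hairpin pairs change the same transcripts, 178 higher and 254 lower, stays open as the biological explanation.

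Serum immediate-early genes were lower with both targets, with a median of -0.42 over all arrays, though the list did not pass camera with an estimated correlation (adjusted p = 0.654 for MYC and 0.846 for PIM1). Removal of the GC trend left 0.9 of this (0.81 to 0.99), which argues against a smooth trend with GC content as the whole cause. Other probes of 12 members changed 0.43 times as much (0.16 to 1.2), and over the 4 with bright other probes the ratio was 3.68 (0.63 to 4.73), which became 0.34 (0.09 to 0.62) over 11 and 3.5 (0.63 to 4.73) over 3 without the ID2 probe whose signals on the PIM1 arrays equal those of other probes, too wide an interval and too few genes to decide on dye bias or cross-hybridization of the single probe. A reduced serum response in cells with either shRNA is a candidate explanation that this design leaves open.

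A hypothesis on the genes lower with MYC and higher with PIM1 shRNA is that cytosine-rich probes carry a signal of their own. Their probes had a median of 43.3% cytosine against 21.7% over all genes. Among 218 unnamed probes of at least 40% cytosine, which had no part in finding the pattern, the median difference was -1.07, against 0.03 for the other unnamed probes, and it was 0.43 times that of these genes (0.32 to 0.58). The medians of these probes were -0.59 and -0.88 on the MYC arrays and 0.33 and 0.59 on the PIM1 arrays. The hypothesis needed at least 0.5, which lies inside the interval. That interval covers the draw of the unnamed probes only. These genes were picked for opposite changes and the unnamed probes were not, which lowers the ratio. The hypothesis may account for much of the pattern and is not settled by this test.

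The spots whose columns disagree were looked for after the values of the target genes had been seen, and no explanation of them was tested. Apart from the MYC, PIM1, FOSL1 and ID2 probes, the stored ratios that depart far include RBM3 on the second MYC array, at -3.27 stored against -0.93 from the processed signals, SUPT4H1 on the first PIM1 array (-1.36 and 0.50) and NEFM on the second (-1.87 and -0.16). FBH1 on the second MYC array and SPOP on the first are the 2 whose stored ratio lies higher, at 1.27 against 0.86 and 1.17 against 0.99. Identical signals were found for EIF2AK2 on the first MYC array and ID2 on the second PIM1 array, for ZEB2, ABI1 and RPL37A on 3 different arrays, and for ZNF644 on the first MYC and the second PIM1 array. Spike-in probes, 10 of them bright, deviated from their mean over the arrays by 0.50, -0.28, -0.95 and 0.73 (log2) on the MYC and PIM1 arrays in order.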
